A study of Mus musculus with 35 samples.

How the data were processed

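Liver RNA of 35 mouse samples in 9 groups of genotype and age was measured on Affymetrix expression arrays with 45101 probe sets. The values are log2 probe set signals that the authors had summarised by RMA (robust multi-array averaging, which corrects background, normalizes and combines the probes of a set), per the submitters' processing notes, which give no version. All 35 columns of values were matched to a sample by name. No pair of arrays had over 5% identical values (0 pairs). Arrays have no read depth, and their number per group, 3 to 5, limits the precision.

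The sorted values fell into 3 distributions, such as separate normalization runs give, and the arrays were treated as 3 runs. The first held the E2f7, E2f8 and E2f7/E2f8 knockouts at 2 months with wild-type replicates 1 to 3, the second the E2f1/E2f2/E2f3 knockout with wild-type replicates 4 and 5, and the last all arrays at 3 weeks. Wild-type arrays at 2 months correlated across genes with a mean r of 0.970 between the runs. The runs were found from the values alone and are not described in the labels.

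Of the probe sets, 64 were Affymetrix controls, 34945 carried 1 gene symbol, 932 several and 9160 none. The controls, and for the tests of genes also the probe sets with several symbols or none, were left out, and each gene was represented by its probe set with the highest mean over all arrays, which gave 18193 genes. The gene table of the GRCm38 assembly matched 34741 probe sets by Entrez identifier, changed 0 symbols and gave a position for 18145 genes, 113 of them by symbol.

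Groups were compared with limma 3.58.1 in R 4.3.3, as group means over all 35 arrays with 1 further term for the second run at 2 months and an intensity trend in the variance (25 residual degrees of freedom, median prior degrees of freedom 5.19). The plan had no term for the runs. It was added once the runs were seen in the distributions and before any model was fitted, so that each knockout was measured against the wild-type arrays of its own run, and the planned fit became an alternative. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The 12 comparisons were the 7 knockouts against wild type, the E2f7/E2f8 against the E2f1/E2f2/E2f3 knockout, wild type between the ages, the departure of the double loss from the sum of the single losses at each age, and the change of the double loss with age. Adjusted p-values of single genes come from limma, and every probe set of the targeted genes was also tested on its own.

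Gene lists, 38 in number, were written from general knowledge of liver and cell cycle biology before the data were examined, as were the comparisons, the rule for naming genes, and the alternatives except those named as added. Of these lists 36 had at least 5 measured members and were tested with camera of limma, with a preset correlation between genes of 0.01 and again with the correlation estimated from the data, adjusted over the lists of a comparison. Members were counted after adjustment over all genes and over the list alone. RNA degradation, as the 3' minus 5' signal of control probe sets, was compared by exact permutation tests (two-sided) in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1; figures used matplotlib 3.10.9. Correlations between effects are across genes and carry no p-value.

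For the E2f7/E2f8 knockouts and the E2f1/E2f2/E2f3 knockout the rule named E2f1, E2f2, E2f3, E2f7 and E2f8, the 10 largest rises and 10 largest falls among called genes whose every knockout array lay beyond every wild-type array, and 2 called members with the smallest adjusted p from each list called by camera. For the other comparisons it named the 5 largest rises and falls and the same list members. Genes with only a clone or predicted name were counted and not named, unless a count of 5 or fewer called for it. The condition on every array was applied within the same run, was not applied to the interactions as planned, and was dropped for the comparison of the E2f7/E2f8 with the E2f1/E2f2/E2f3 knockout. Gm2788, Mettl21a, some values of B4galnt1, Trhde and Yae1d1, and list members beyond 2 per list were chosen after their values were seen.

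In a test 200 of 18193 simulated genes were changed, 50 each by 0.5, 1, 2 and 4 log2. The E2f7/E2f8 comparison recovered 38, 48, 50 and 50 at 3 weeks with 7 false calls. At 2 months these were 42, 49, 50 and 50 with 12. The E2f1/E2f2/E2f3 comparison had 30, 47, 50 and 50 with 10. Other splits of their real arrays gave up to 846 calls, so real error may exceed this.

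Alternatives were fits of only the groups compared, quantile normalization of all 35 arrays, leaving out the dimmest 40 percent of genes, the mean of a gene's probe sets, no intensity trend, array weights, the replicate number as a block, and leaving out each array in turn, where an array outside a comparison's groups or run acts on it only through the estimated spread. Fits with only the arrays of 1 run were added later. A sex covariate was not fitted, since signal of Y-linked genes was present in all arrays. Called genes among the 100 on either side of a targeted locus were counted with Fisher's exact test (one-sided), and at most 100 other splits of the arrays were fitted per comparison.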

Results

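Liver RNA was measured on 35 Affymetrix mouse expression arrays that fell into 9 groups of genotype and age. At 3 weeks and again at 2 months there were 4 arrays each of livers lacking E2f7, E2f8 or both, deleted with Albumin-Cre, a recombinase line active in hepatocytes, on an FVB background. E2f7 and E2f8 are atypical E2F proteins, which repress cell cycle genes. The wild-type FVB livers gave 3 arrays at 3 weeks and 5 at 2 months. A further 3 arrays at 2 months came from livers lacking E2f1, E2f2 and E2f3, the activating E2F proteins, made with the interferon-inducible Mx1-Cre line on a mixed C57BL/6 and FVB background. The labels number the arrays of a group as separate samples without stating that each came from its own animal, so the errors measure the spread between these samples. Signals are log2 values of 18193 genes.

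The arrays fell into 3 distributions of values, such as separate normalization runs give, and are called runs here. The sorted log2 values of 2 arrays differed on average by 0.0203, 0.0313 and 0.033 within the runs. The gap was 0.122 between the runs at 2 months, and 0.801 and 0.745 between these and the 3-week run. The 2-month runs differed in more than normalization: control Gapdh had a 3' minus 5' signal of 1.62 to 1.99 log2 in the first and 0.27 to 0.55 in the second, and control Actb went the other way, from 0.19 to 0.41 and from 0.91 to 1.26. Whether the runs match hybridization batches is not given in the sources used here. The E2f1/E2f2/E2f3 knockout shared its run with wild-type replicates 4 and 5, and the other 2-month knockouts theirs with replicates 1 to 3. Knockouts were therefore compared with the wild-type arrays of their own run. All arrays carried signal of Y-linked genes, with a mean between 6.68 and 7.64 log2, and a measure of RNA degradation from the control probe sets was compared between each of the 7 knockout groups and wild type. The lowest p of the exact permutation tests (two-sided) was 0.200, in the E2f7 knockout at 3 weeks, where the 35 splits allow 0.0286. The 10 splits of the E2f1/E2f2/E2f3 knockout arrays allow only 0.10 and gave 0.50.

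The targeted genes were examined first. The brightest E2f8 probe set had a higher mean in each group where E2f8 was deleted. In the E2f8 knockout it rose by 1.80 log2 at 3 weeks (SE 0.35, 8.95 ± 0.24 SD, n = 4, against 7.15 ± 0.67, n = 3) and by 2.20 at 2 months (SE 0.35, 10.13 ± 0.39 against 7.93 ± 0.59), with limma adjusted p = 0.00549 and 0.00178. In the E2f7/E2f8 knockout it rose by 1.58 at 3 weeks (SE 0.35, adjusted p = 0.0349), a call lost without knockout replicate 1 or 2 or wild-type replicate 2 or 3, where the highest adjusted p was 0.215. At 2 months its difference of 1.33 (SE 0.35) did not pass, with adjusted p = 0.453. The call in the E2f8 knockout at 2 months ended without wild-type replicate 2, at adjusted p = 0.0572. A second E2f8 probe set rose by 1.34 and 0.93 in the E2f8 knockout at 3 weeks and 2 months (SE 0.29 each, adjusted p = 0.0216 and 0.368 over all probe sets). Gm2788, a non-coding RNA gene that overlaps E2f8 in the GRCm38 annotation, went the other way in every group without E2f8. It stood at -3.74 in the E2f8 knockout and at -3.66 in the E2f7/E2f8 knockout at 3 weeks (SE 0.43 each, 5.71 ± 0.21 and 5.79 ± 0.14 against 9.45 ± 0.40) and at -3.32 and -3.38 at 2 months (SE 0.43 each), with adjusted p at or below 0.000150, and was chosen after its values were seen. No probe set of E2f1, E2f2, E2f3 or E2f7 passed in either direction where its gene was targeted. E2f7 differed by 0.01 and -0.17 in the E2f7 knockout at 3 weeks and 2 months (SE 0.15 each, adjusted p = 0.990 and 0.907) and by -0.15 and -0.23 in the E2f7/E2f8 knockout (SE 0.15 each), and E2f1, E2f2 and E2f3 by 0.11, 0.15 and 0.10 in their combined knockout (SE 0.14 to 0.15, adjusted p between 0.690 and 0.815), with the other probe sets of these 3 genes between -0.06 and 0.04. Which exons the probes cover relative to the deleted parts is not given in the sources used here, and a probe outside the deleted part checks nothing.

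**Figure D1:**
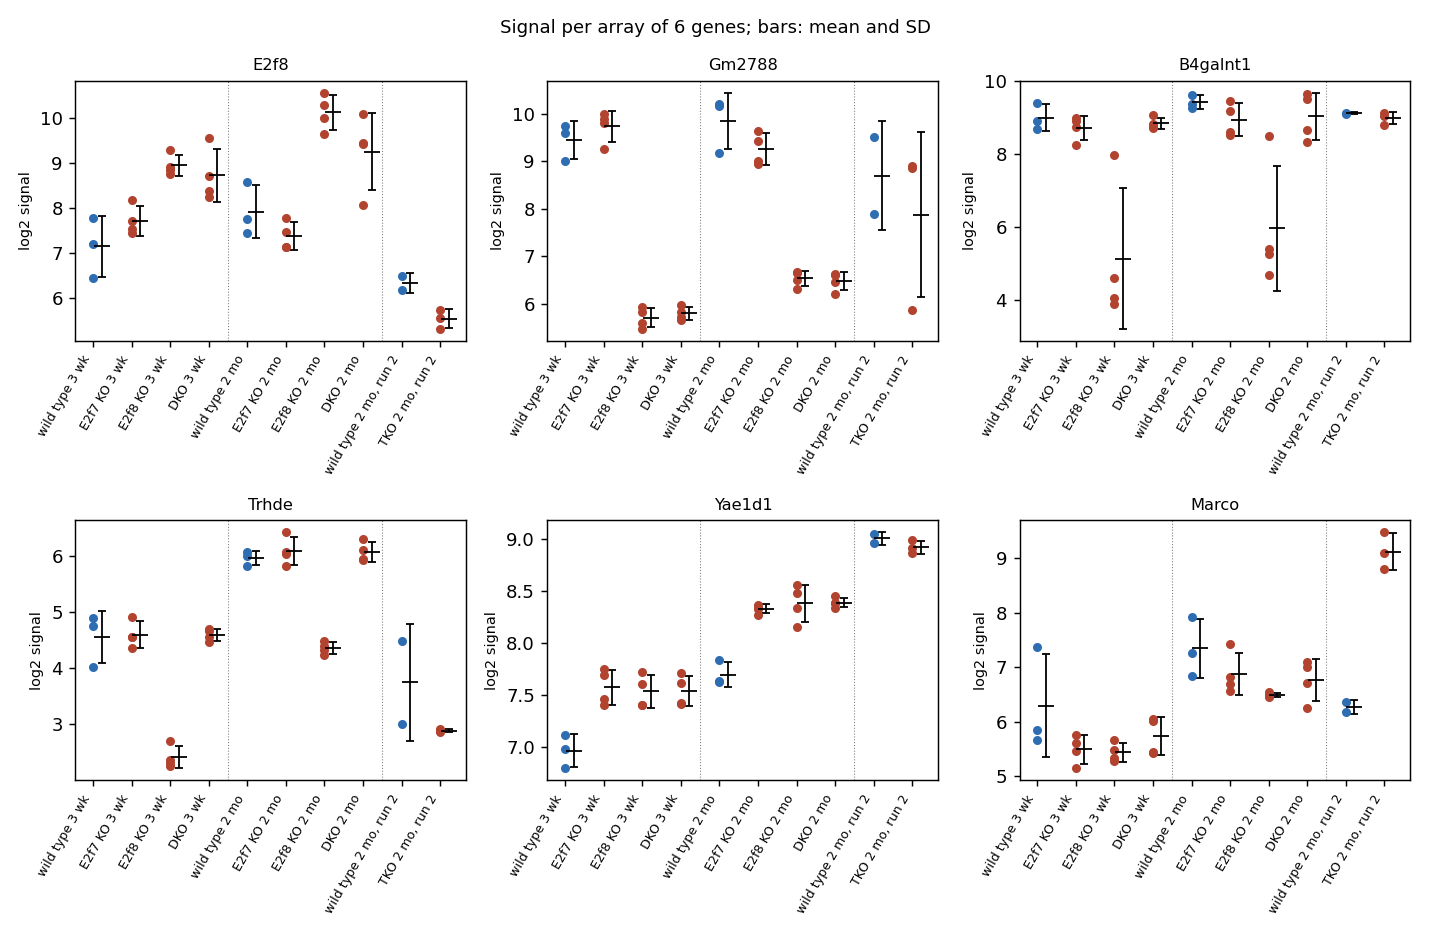
Log2 signal per array (y axis) of E2f8, Gm2788, B4galnt1, Trhde, Yae1d1 and Marco in each group (x axis), with dotted lines between the 3 normalization runs; points are arrays, wild type in blue and knockouts in red, and bars give the mean and SD. E2f8 signal was 8.95 ± 0.24 in the E2f8 knockout at 3 weeks against 7.15 ± 0.67 in wild type, while Gm2788, which overlaps E2f8, was at 5.71 ± 0.21 against 9.45 ± 0.40.

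The E2f7/E2f8 knockout was compared with wild type (n = 4 against 3) at 3 weeks, when liver cells still divide. Pclaf, which encodes a partner of the replication clamp PCNA, rose by 1.40 log2 (SE 0.22, adjusted p = 0.00277), and Cdkn2c, an inhibitor of CDK4 and CDK6, rose by 0.64 (SE 0.13). Psat1 of serine synthesis rose by 1.28 (SE 0.29), the protocadherin Pcdh17 by 0.87 (SE 0.13) and the Wnt receptor Fzd5 by 0.66 (SE 0.12), beside Akr1c19, Alg2, Clcn6 and Sgsm1 at 0.62 to 1.02. The MHC class II genes H2-Aa and H2-Ab1 fell by 1.11 and by 0.90 (SE 0.22 each), the transcription factor Maf fell by 0.59 (SE 0.14) and the coagulation inhibitor Tfpi fell by 0.64 (SE 0.15). Plscr2, Sult1b1, Nxt2, Cmtm3, Akr1c14 and Ppm1k fell by 0.55 to 0.72. Pclaf, Pcdh17 and Fzd5 kept their calls with each array left out in turn, while the other genes named here lost theirs in 2 to 5 of the 7 fits, with adjusted p up to 0.269, for Maf. In all, 118 of 18193 genes were called by limma, 80 higher and 38 lower.

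Among gene lists, mitosis and cytokinesis genes lay higher at 3 weeks in the E2f7/E2f8 knockout, in 54 of 62 members, with a median of 0.23. Their camera adjusted p was 3.31e-07 with the preset correlation and adjusted p = 0.570 with an estimated correlation, and the members stayed short of the threshold over all genes and adjusted over the list alone. Sinusoidal endothelial markers lay lower in 21 of 21 members (median -0.33, 0 called over all genes, 7 adjusted over the list alone) and macrophage and Kupffer cell markers in 17 of 18 (median -0.28, with only Cd5l at -0.68 passing adjusted over the list alone). For both, adjusted p = 0.479 with an estimated correlation. Genes of bile acid synthesis and transport (median -0.21, Slco1b2 at -0.47 passing adjusted over the list alone), PPAR alpha targets (-0.15), p53 targets (-0.10) and strain-variable genes (-0.05, with H2-Aa and H2-Ab1 called) also lay lower, again with adjusted p = 0.479 with an estimated correlation. Female-biased liver genes had a median of -0.32, with adjusted p = 0.520 with an estimated correlation. Without wild-type replicate 3 the mitosis call ended, at a median of 0.09 and adjusted p = 0.139, and the endothelial and macrophage medians were -0.21 and -0.16. Without wild-type replicate 1 the calls of PPAR alpha (adjusted p = 0.210) and p53 targets (0.425), strain-variable and female-biased genes ended. So did those of bile acid genes without knockout replicate 2 (0.0806) and of female-biased genes without knockout replicate 1 (0.125). Strain-variable genes lost theirs without wild-type replicate 2 (0.180), as did PPAR alpha, p53 and strain-variable lists without knockout replicate 4. The count of 118 fell to 3 when only arrays of the 3-week run were fitted, to 1 with only these 2 groups and to 8 without a term for the runs. It was 58, 13, 56 and 291 without knockout replicates 1 to 4, and 549, 27 and 33 without wild-type replicates 1 to 3.

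Loss of E2f7 alone was compared with wild type at 3 weeks (n = 4 against 3). Yae1d1 rose by 0.61 log2 (SE 0.10, adjusted p = 0.00664) and Mettl21a, chosen after its values were seen, by 0.49 (SE 0.10). Akr1c14, a hydroxysteroid dehydrogenase, fell by 0.67 (SE 0.11, adjusted p = 0.00664). Aldh6a1 of valine catabolism fell by 0.51 (SE 0.07), the B cell survival factor Tnfsf13b fell by 0.56 (SE 0.11), Nutm1 fell by 0.58 (SE 0.10) and C1d fell by 0.45 (SE 0.09). In all 8 genes were called, 2 higher and 6 lower. C1d, Tnfsf13b, Nutm1, Yae1d1 and Akr1c14 lost their calls in 5, 3, 3, 3 and 2 of 7 fits without single arrays, with adjusted p up to 0.356. Proliferation lists lay higher: DNA replication genes in 49 of 54 members (median 0.24, Pole2 and Fen1 passing adjusted over the list alone) and mitosis genes in 60 of 62 (median 0.23), both with adjusted p = 0.729 with an estimated correlation. DNA repair genes did so in 25 of 29 (median 0.16, Rad54l and Rad18 passing adjusted over the list alone), with adjusted p = 0.436 with an estimated correlation. Macrophage markers lay lower in 18 of 18 members (median -0.40, 7 passing adjusted over the list alone), with adjusted p = 0.486 with an estimated correlation. Hepatocyte genes had a median of -0.06 (Cps1 and Tdo2 passing adjusted over the list alone), with adjusted p = 0.111 with an estimated correlation. Fatty acid synthesis (median 0.35), endothelial (-0.16) and pericentral genes (-0.13) each had adjusted p = 0.729 with an estimated correlation. Wild-type replicate 3 had a mean of the replication genes of 6.58, against 6.95 and 7.03 in the others. Without it the calls of the replication (median 0.11, adjusted p = 0.0618), mitosis (0.07, 0.293), fatty acid synthesis (0.13, 0.347), endothelial (-0.09, 0.326) and pericentral lists (-0.07, 0.347) ended, the last also without knockout replicate 1 or 3. Without wild-type replicate 3 the repair and macrophage medians were 0.10 and -0.23. With only 3-week arrays in the fit 0 genes were called, with only the arrays of the 2 groups also 0, where the full limma fit gave 2036 genes with an unadjusted p under 0.05, and without a run term 2. The count was 265, 1 and 1 without wild-type replicates 1 to 3, and 2 and 36 without knockout replicates 3 and 4.

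Loss of E2f8 alone was likewise compared with wild type at 3 weeks (n = 4 against 3). Angptl8, an insulin-induced regulator of lipoprotein lipase, rose by 2.48 log2 (SE 0.43, adjusted p = 0.00207), the steroid dehydrogenase Hsd3b1 rose by 1.72 (SE 0.33), the manganese exporter Slc30a10 by 1.35 (SE 0.21) and Slc16a6 by 1.12 (SE 0.25). B4galnt1, a ganglioside synthase, fell by 3.88 (SE 0.66, adjusted p = 0.00207), and Trhde, a peptidase that degrades thyrotropin-releasing hormone, fell by 2.14 (SE 0.21, adjusted p = 4.50e-07). Rgs16 fell by 3.58 (SE 0.78), Igfbp1 fell by 2.18 (SE 0.54) and the heat shock gene Hspa1b fell by 1.92 (SE 0.45); the wild-type arrays spread widely in these, with SDs of 2.19, 1.56 and 1.11. B4galnt1 and Trhde were near wild type in the E2f7/E2f8 knockout, at -0.15 (SE 0.66) and 0.04 (SE 0.21). Igfbp1, Hspa1b, Rgs16 and Slc16a6 lost their calls in 5, 4, 2 and 2 of 7 fits without single arrays, with adjusted p up to 0.186. In all 347 genes were called, 160 higher and 187 lower. Without wild-type replicate 1 the count was 261, against 265 in the E2f7 knockout without that array, and whether the single losses differ from each other was not tested.

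Macrophage markers lay lower in 18 of 18 members in the E2f8 knockout at 3 weeks (median -0.42). Adgre1 fell by 0.58 and Aif1 fell by 0.60, 16 did not pass, and 8 passed adjusted over the list alone. Endothelial markers lay lower in 21 of 21 (median -0.26), with Bmp2 called (it fell by 0.79, SE 0.20) and Bmp2, Stab2 and Fcgr2b passing adjusted over the list alone. Genes of the unfolded protein response lay higher in 15 of 21 (median 0.29), 0 called over all genes and 10 higher and 2 lower adjusted over the list alone. These 3 lists had adjusted p = 0.638 with an estimated correlation, as did erythroid genes (median -0.14, Slc4a1 fell by 1.08 and Tfrc rose by 1.05), polyploidy and cytokinesis regulators (0.18, E2f8 itself called, with Prc1 and Fbxo5 adjusted over the list alone), xenobiotic genes (-0.12, Cyp2b9 passing adjusted over the list alone) and bile acid genes (-0.19, Abcg5 fell by 0.52, Slc27a5 also passing adjusted over the list alone). Mitosis genes (median 0.22, higher in 55 of 62) and stellate cell genes (-0.10) each had adjusted p = 0.656 with an estimated correlation. Without wild-type replicate 3 the calls of mitosis (median 0.07, adjusted p = 0.137), erythroid (0.102), polyploidy (0.249), stellate (0.433) and bile acid genes ended. The same held without wild-type replicate 1 for the unfolded protein response (0.130), xenobiotic, bile acid and stellate genes, without knockout replicate 4 for bile acid (0.261), xenobiotic (0.235) and stellate genes, and without knockout replicate 3 for bile acid, stellate and polyploidy genes. Stellate genes lost their call without knockout replicate 1 also, and bile acid genes without wild-type replicate 2. The macrophage median was -0.26 without knockout replicate 4 and -0.28 without wild-type replicate 3. Abcg5, Bmp2, Adgre1, Aif1 and Slc4a1 lost their calls in 5, 4, 3, 2 and 2 of 7 such fits, with adjusted p up to 0.243. The count of 347 was 125 with only 3-week arrays, 23 with only the arrays of the 2 groups, 115 without a run term and 161 with array weights. It was 166 without knockout replicate 1 and 215 without knockout replicate 4.

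Whether the loss of both genes departed from the sum of the single losses was tested as an interaction. The same wild-type arrays enter each effect, so a shift that all knockouts share against wild type also gives an interaction, of opposite sign. At 3 weeks 23 genes were called, 15 higher and 8 lower than the sum. Trhde stood 2.14 log2 above it (SE 0.29, adjusted p = 0.000398), its level being low only in the E2f8 knockout among the 4 genotypes. Gstt2, a glutathione transferase, stood 1.31 above (SE 0.22), Npl of sialic acid breakdown 1.25 (SE 0.23), the glycogen synthase Gys2 0.97 (SE 0.16) and Pcdh17 0.93 (SE 0.17). Ildr2 stood at -2.82 (SE 0.48), Ephb6 at -2.01 (SE 0.30), the threonyl-tRNA synthetase Tars at -1.0 (SE 0.21), Cfhr3 at -0.88 and Pafah1b3 at -0.74. Macrophage markers stood above the sum in 18 of 18 members (median 0.52) and p53 targets below it in 19 of 24 (-0.20). Erythroid genes had a median of 0.20. Adgre1, Marco, Aif1 and Spic of the first and Slc4a1 and Rhag of the last passed adjusted over their list alone. With an estimated correlation the lists had adjusted p = 0.409, 0.409 and 0.0725. Medians were -0.23, -0.16, -0.17 and -0.22 for mitosis, replication, DNA repair and polyploidy genes, and adjusted p likewise 0.797, 0.797, 0.463 and 0.604. These 4 lists and p53 targets each lost their call without E2f7/E2f8 knockout replicate 1 or wild-type replicate 3, with adjusted p up to 0.442 for mitosis and 0.434 for replication genes and 0.395 for the other 3. The p53 call also ended without E2f7 knockout replicate 1 or wild-type replicate 2, and the polyploidy call without E2f7 knockout replicate 4 or E2f8 knockout replicate 3. Cfhr3, Tars, Pafah1b3, Pcdh17 and Npl lost their calls in 11, 9, 6, 2 and 1 of 15 fits without single arrays, with adjusted p up to 0.176. The count of 23 was 2 with only 3-week arrays or only the 4 groups, and 1 without a run term. It was 14 and 8 without E2f7 knockout replicates 1 and 3, 14 without E2f7/E2f8 knockout replicate 3 and 10 without wild-type replicate 3.

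At 2 months the E2f7/E2f8 knockout was again compared with wild type (n = 4 against 3). Only 2 genes were called, Yae1d1, which rose by 0.69 log2 (SE 0.10, adjusted p = 0.00108), and Gm2788. Neither lost its call when any single array was left out, but Yae1d1 did with the mean of its probe sets, at 0.27 (adjusted p = 0.785), and without a run term, at 0.17 (adjusted p = 0.608). Interferon-responsive genes lay higher in 35 of 37 members (median 0.24, 0 called, 6 passing adjusted over the list alone). Endothelial markers lay lower in 19 of 21 (median -0.28, Fcgr2b and Aqp1 passing adjusted over the list alone) and macrophage markers in 18 of 18 (median -0.29). For these 3 lists adjusted p = 0.349 with an estimated correlation. Cholesterol synthesis genes (median 0.16) and mitosis genes (0.07) had adjusted p = 0.874, stellate cell genes (-0.08) adjusted p = 0.833 and periportal genes (0.09) adjusted p = 0.362 with an estimated correlation. The cholesterol call ended without wild-type replicate 3 (adjusted p = 0.895) or knockout replicate 2, 3 or 4, and the mitosis call without knockout replicate 2 (0.347) or 4 or wild-type replicate 1 or 3. The stellate call ended without knockout replicate 1 (0.222) or 3 or wild-type replicate 1 or 3, and the periportal call without knockout replicate 4 (0.161) or wild-type replicate 1 or 2. The endothelial median was -0.14 without wild-type replicate 3. The count of 2 was 13 with array weights, 6 without a run term, 1 with the mean of a gene's probe sets, and 5, 4 and 4 without knockout replicates 1, 3 and 4.

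In the E2f7 knockout at 2 months (n = 4 against 3) camera called 2 lists of stress responses also with an estimated correlation. Acute phase genes, liver genes induced by inflammation, lay lower in 23 of 23 members (median -0.52, 0 called over all genes, 16 passing adjusted over the list alone), with camera adjusted p = 2.41e-27 and adjusted p = 0.00810 with an estimated correlation. Genes of the unfolded protein response lay lower in 20 of 21 (median -0.40, 16 passing adjusted over the list alone), with adjusted p = 0.00518 with an estimated correlation. The mean acute phase signal of wild-type replicates 1 and 2 was 12.36 and 12.23 log2 against 10.85 in replicate 3, so that 1 of the 3 wild-type arrays lay among the knockout arrays. Heat shock genes lay lower (median -0.55), with adjusted p = 0.249 with an estimated correlation, as did macrophage markers in 18 of 18 members (-0.36), with adjusted p = 0.129. Fatty acid synthesis genes lay higher (median 0.45, with Acacb, Elovl5, Gpam and Acss2 passing adjusted over the list alone), with adjusted p = 0.414 with an estimated correlation. Cholesterol synthesis genes (0.25) had adjusted p = 0.697, xenobiotic genes (0.12, Gsta2, Gsta4, Gstm1 and Gstm3 passing adjusted over the list alone) adjusted p = 0.383, and interferon genes (-0.07) adjusted p = 0.808 with an estimated correlation. PPAR alpha targets (0.08, Acaa1b passing adjusted over the list alone) had adjusted p = 0.544, bile duct and gut epithelium genes (0.19) adjusted p = 0.104 and adipose genes (0.11, Pparg passing adjusted over the list alone) adjusted p = 0.129 with an estimated correlation. Without wild-type replicate 3 the medians were -0.82 for acute phase and -0.35 for heat shock genes, and the cholesterol call ended (median 0.12, adjusted p = 0.422). Without wild-type replicate 1 those of interferon (0.903), PPAR alpha (0.340), xenobiotic and adipose genes (0.139) ended. So did those of PPAR alpha and xenobiotic genes without wild-type replicate 2 (0.123 for the latter) or knockout replicate 4, and of interferon genes without knockout replicate 1, 2 or 4. The single gene called was Yae1d1, which rose by 0.63 (SE 0.10, adjusted p = 0.0111). The count of 1 was 40 without a run term and 59 with array weights. It was 0, 0, 2 and 2 without knockout replicates 1 to 4, and 0, 0 and 39 without wild-type replicates 1 to 3, with adjusted p up to 0.187 for Yae1d1. The full limma fit gave 1279 genes with an unadjusted p under 0.05.

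Loss of E2f8 alone at 2 months was compared with wild type (n = 4 against 3). The acyl-CoA thioesterases Acot3 and Acot2 rose by 2.31 (SE 0.51) and 0.75 log2 (SE 0.17), the acyltransferase Acnat2 rose by 1.84 (SE 0.30, adjusted p = 0.00198), the lipid transfer gene Osbpl3 by 1.45 (SE 0.23) and Cyp2c38 by 1.37 (SE 0.30). The acute phase genes Saa2, Orm2 and Saa1 stood at -3.55 (SE 0.78), -3.28 (SE 0.59) and -2.65 (SE 0.54), against wild-type SDs of 2.65, 2.45 and 1.80. B4galnt1 fell by 3.47 (SE 0.66) and Trhde fell by 1.61 (SE 0.21, adjusted p = 0.000126), and Yae1d1 rose by 0.68 (SE 0.10). The macrophage genes Cd5l and C1qb fell by 0.94 (SE 0.20) and by 0.84 (SE 0.19). In all 64 genes were called, 38 higher and 26 lower. B4galnt1 lost its call without knockout replicate 2 or 4 or wild-type replicate 1 or 2, where the highest adjusted p was 0.128. Acot2, Acot3, Cyp2c38, Cd5l, Saa1 and Saa2 lost theirs in 5 of 9 fits without single arrays, C1qb in 4 and Orm2 in 2, with adjusted p up to 0.374.

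Macrophage markers lay lower in 18 of 18 members in the E2f8 knockout at 2 months (median -0.61, 2 called over all genes, Cd5l and C1qb, 16 not passing, 15 lower adjusted over the list alone), with camera adjusted p = 2.29e-23 and adjusted p = 0.0481 with an estimated correlation. Acute phase genes lay lower in 19 of 23 (median -0.44, Saa1, Saa2 and Orm2 called, 13 adjusted over the list alone), with adjusted p = 0.0652 with an estimated correlation. The low acute phase mean of wild-type replicate 3, 10.85, lay within the range of these knockout arrays, 10.84 to 10.94. Fatty acid synthesis genes lay higher in 19 of 20 (median 0.51, Elovl5, Pklr and Agpat2 passing adjusted over the list alone), with adjusted p = 0.194 with an estimated correlation. PPAR alpha targets lay higher in 22 of 25 (median 0.12, Acot2 and Acot3 called, 5 adjusted over the list alone, which add Acaa1b, Acadm and Acot1). Unfolded protein response genes lay lower (median -0.22, Asns passing adjusted over the list alone) and periportal genes higher (0.08, Hal, Etnppl, Sfxn1 and Serpina6 passing adjusted over the list alone). For these 3 lists adjusted p = 0.138 with an estimated correlation. Female-biased liver genes (0.13, Acot3 called, with Trim24 and Ntrk2 adjusted over the list alone) had adjusted p = 0.314, stellate cell genes (-0.18, Lum and Dcn passing adjusted over the list alone) adjusted p = 0.485 and leukocyte genes (-0.06, Ptprc and Laptm5 passing adjusted over the list alone) adjusted p = 0.641 with an estimated correlation. Xenobiotic (0.13) and mitosis genes (0.07) had adjusted p = 0.515 and 0.824, and endothelial (-0.15) and neutrophil genes (-0.07) adjusted p = 0.743 with an estimated correlation. The endothelial call ended without wild-type replicate 3 (median -0.02, adjusted p = 0.849) or knockout replicate 4. The neutrophil call ended without wild-type replicate 2 (0.428) or 1 or knockout replicate 4, and the leukocyte call without knockout replicate 4 (0.241) or wild-type replicate 1 or 3. The mitosis call ended without knockout replicate 1 (0.335) or wild-type replicate 1 or 3, and the xenobiotic call without wild-type replicate 2 (0.197) or 1 or knockout replicate 1, 2 or 4. The acute phase median was -0.29, -0.27 and -0.73 without wild-type replicates 1 to 3, the PPAR alpha median 0.06 without replicate 1, the female-biased median 0.22 without replicate 2 and the stellate median -0.07 without knockout replicate 4. Without knockout replicate 1 the periportal median was 0.15. The count of 64 was 111 with only arrays of its run, 35 with only the 2 groups, 282 without a run term and 252 with array weights. It was 22, 23 and 15 without knockout replicates 1, 2 and 4, and 14, 7 and 100 without wild-type replicates 1 to 3.

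At 2 months the interaction of the 2 losses was called in 199 genes, 107 above and 92 below the sum of the single losses. Acute phase genes stood above it in 22 of 23 members (median 0.87). The arrays spread widely in this list, from 10.85, in replicate 3, to 12.36 in wild type and from 11.15 to 12.26 in the E2f7/E2f8 knockout. Saa2, with a wild-type SD of 2.65, stood 6.17 log2 above the sum (SE 1.07, adjusted p = 0.00355), Lcn2 5.71 (SE 1.08), Orm2 5.11 (SE 0.81) and Saa1 4.85 (SE 0.74), 11 members were called above, 12 did not pass, and 18 passed adjusted over the list alone. Genes of the unfolded protein response stood above in 20 of 21 (median 0.68), with Herpud1, Sdf2l1, Pdia6 and Calr called and 16 passing adjusted over the list alone. Both lists had adjusted p = 0.00642 with an estimated correlation. Below the sum, Gdpd3 stood at -2.95 (SE 0.50), Osbpl3 at -2.83 (SE 0.31, adjusted p = 5.54e-06), Acaa1b at -1.03 (SE 0.16), Acot2 at -1.02 (SE 0.23), Elovl5 at -0.92 (SE 0.21) and the adipogenic factor Pparg at -1.31 (SE 0.25). The succinate receptor Sucnr1 stood at -3.17 (SE 0.56), Gsta2 at -2.69 (SE 0.57), Cyp2c39 at -2.50 (SE 0.55) and Gstm1 at -0.52 (SE 0.11), and B4galnt1 at 3.57 (SE 0.91). Fatty acid synthesis genes (median -0.90, 14 of 20 passing adjusted over the list alone) and xenobiotic genes (-0.25) had adjusted p = 0.135, and macrophage markers (0.67, higher in 18 of 18, C1qb called at 1.03) and PPAR alpha targets (-0.21) adjusted p = 0.107 with an estimated correlation. Interferon genes (0.24, with Usp18 at 1.97, Ifi27l2a at 1.25 and Lgals3bp at 0.84 called) and heat shock genes (0.53) had adjusted p = 0.290, neutrophil genes (0.09) adjusted p = 0.413, female-biased genes (-0.21) adjusted p = 0.473 and adipose genes (-0.12) adjusted p = 0.148 with an estimated correlation. The female-biased call ended without replicate 4 of the E2f7 (adjusted p = 0.0801) or E2f8 knockout, E2f7/E2f8 knockout replicate 3 or wild-type replicate 3. The neutrophil call ended without wild-type replicate 2 (0.101), and the adipose call without wild-type replicate 3 (0.0721) or 1, E2f7 knockout replicate 2, E2f8 knockout replicate 1 or E2f7/E2f8 knockout replicate 3. The heat shock median was 0.34 without E2f7 knockout replicate 3 and 0.35 without E2f7/E2f8 knockout replicate 1. The PPAR alpha median was -0.14 without wild-type replicate 1 and the female-biased median -0.44 without E2f7/E2f8 knockout replicate 4. The count of 199 was 582 with array weights. It was 132 without E2f7 knockout replicate 1, 127 without E2f8 knockout replicate 4, 106 without E2f7/E2f8 knockout replicate 1, and 60 and 64 without wild-type replicates 1 and 2. B4galnt1 lost its call in 12 of 17 such fits, with adjusted p up to 0.120. The number was 10 for C1qb and Pdia6, 8 for Ifi27l2a, 5 for Acot2, Elovl5 and Usp18, 3 for Sdf2l1 and 2 for Gsta2, Gstm1 and Cyp2c39, with adjusted p up to 0.136.

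**Figure D2:**
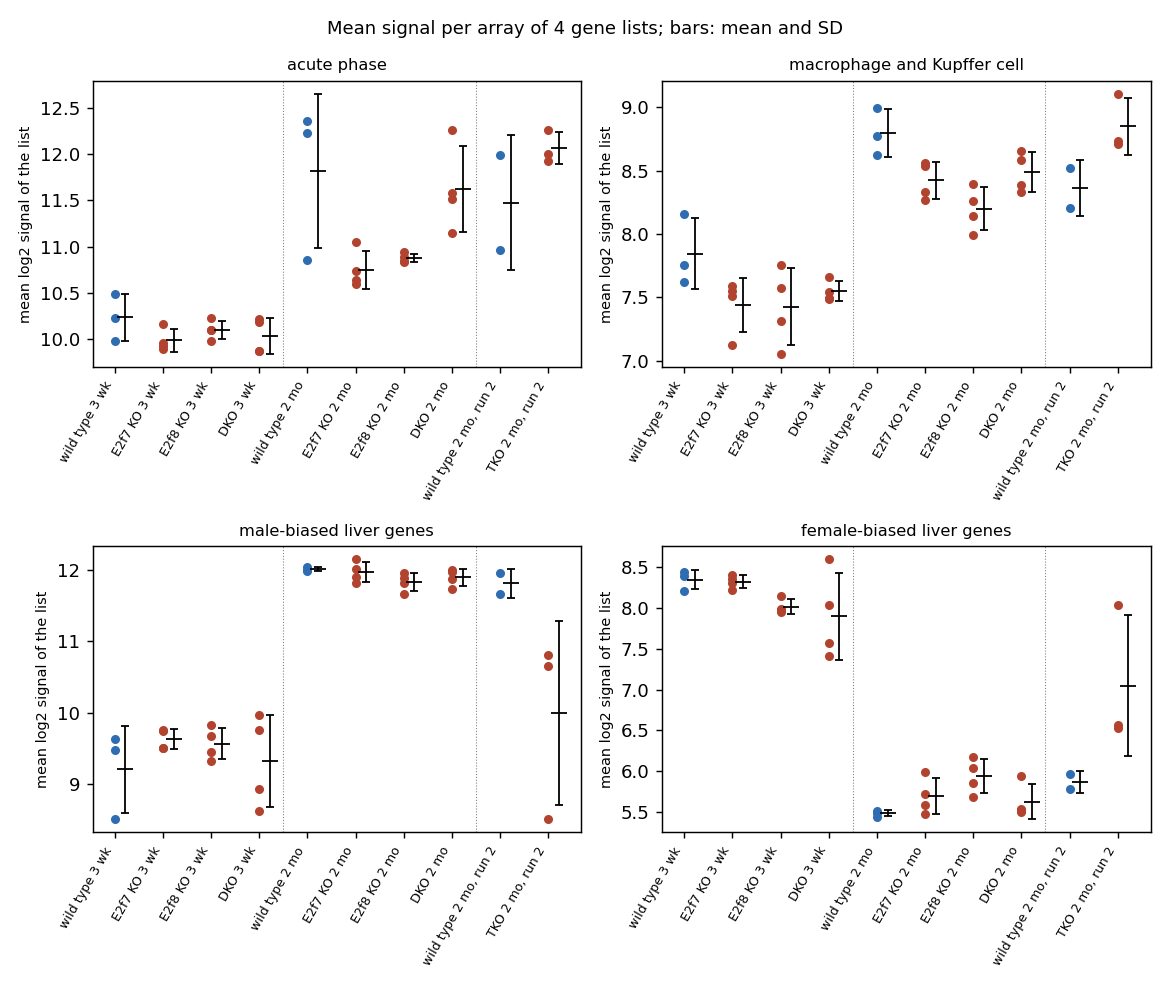
Mean log2 signal of 4 gene lists per array (y axis) in each group (x axis), with dotted lines between the 3 normalization runs; points are arrays, wild type in blue and knockouts in red, and bars give the mean and SD. In the first run at 2 months wild-type replicates 1 and 2 had acute phase means of 12.36 and 12.23 and replicate 3 had 10.85.

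The effects of losing both E2f7 and E2f8 were compared between the ages. Across genes, which are not independent replicates, the log2 changes correlated with Pearson's r = 0.204 and Spearman's rho = 0.143, and the called genes shared were Yae1d1, higher at both ages, and Gm2788, lower at both. The difference between the ages was called for 1 gene, Pcdh17, which rose by 0.87 at 3 weeks and stood 1.03 log2 lower in its effect at 2 months (-1.03, SE 0.18, adjusted p = 0.0394). That count was 0 to 4 when single arrays were left out, and the call of Pcdh17 ended in 8 of 16 such fits, with adjusted p up to 0.161. It was 0 in the fits of only the groups compared, after quantile normalization, without dim genes and with the mean of probe sets, against 1325 genes with an unadjusted p under 0.05 in the full limma fit. In the E2f8 knockout 13 genes were called at both ages, 4 higher and 8 lower at both and Plscr2 in opposite directions, against 0.334 and 0.267 for independent lists in each direction (r = 0.208).

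**Figure D3:**
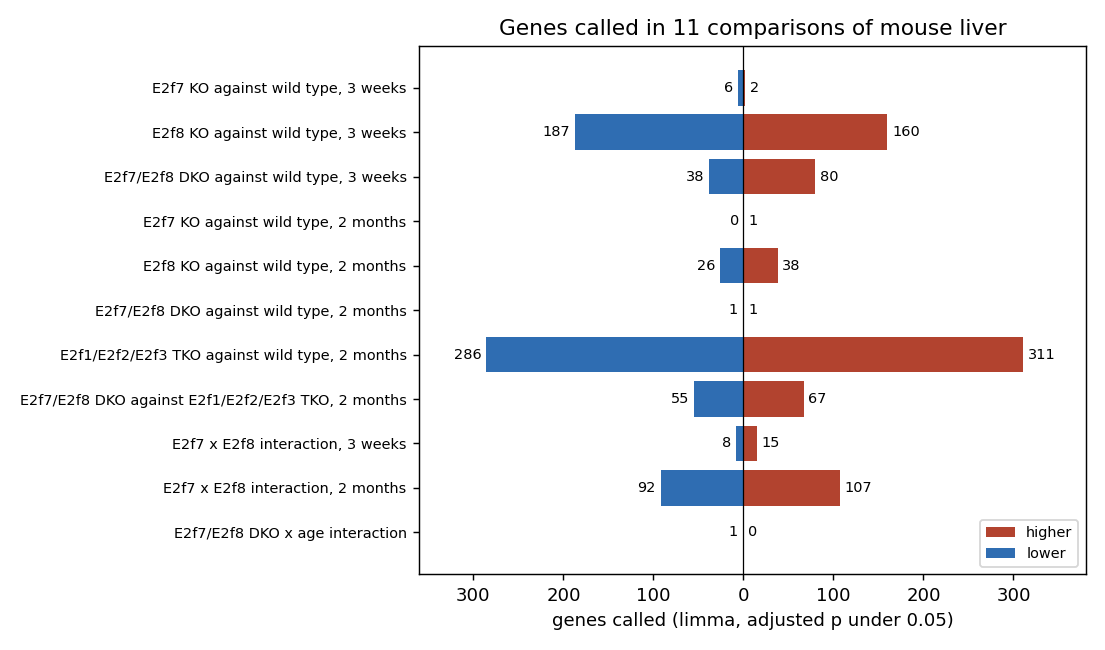
Number of genes called by limma at adjusted p under 0.05 (x axis, higher to the right in red, lower to the left in blue) in 11 comparisons (y axis). The E2f1/E2f2/E2f3 knockout had the most calls, 311 higher and 286 lower, and the E2f7/E2f8 knockout at 2 months had 1 of each.

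Livers lacking E2f1, E2f2 and E2f3 (n = 3) were compared with the 2 wild-type arrays of their run. Of the 15 male-biased genes 15 lay lower (median -1.50), 7 fell, 8 did not pass, and 12 passed adjusted over the list alone: Serpina4-ps1 fell by 4.24 log2 (SE 0.79, adjusted p = 0.00176), Ugt2b38 fell by 3.83 (SE 0.78), Hsd3b5 fell by 3.11 (SE 0.84) and Elovl3 fell by 3.05 (SE 0.87). Of the 17 female-biased genes 16 lay higher (median 1.00, 9 adjusted over the list alone), and Cyp2b9, Slc22a26 and Atp6v0d2 rose by 4.59 (SE 1.30), 1.42 (SE 0.38) and 1.41 (SE 0.35). The camera adjusted p was 1.66e-12 and 3.48e-07, and adjusted p = 0.0703 and 0.0959 with an estimated correlation. Replicate 3 stood apart, with a mean of the male-biased genes of 8.52 against 10.66 and 10.81 in the other 2 and 11.96 and 11.66 in wild type. Without it the median was -0.76, and that of the female-biased genes 0.56. Elovl3 and Cyp2b9 lost their calls in 6 of 8 fits without single arrays, Hsd3b5 and Slc22a26 in 3, Atp6v0d2 in 2 and Serpina4-ps1 and Ugt2b38 in 1, with adjusted p up to 0.284.

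Targets of p53 lay higher in 19 of 24 members in the E2f1/E2f2/E2f3 knockout (median 0.39, camera adjusted p = 1.35e-07, adjusted p = 0.0126 with an estimated correlation), 5 rose, Perp fell by 0.68, 18 did not pass, and 11 were higher and 1 lower adjusted over the list alone. The growth arrest gene Cdkn1a rose by 1.82 (SE 0.52), the p53-induced gene Phlda3 by 1.16 (SE 0.12, adjusted p = 6.34e-07), the receptor Eda2r by 1.33 (SE 0.23), Mdm2 by 0.58 and Polk by 0.63. DNA replication genes lay higher in 47 of 54 (median 0.39), and Mcm2, Mcm5, Cdt1, Gins1, Rfc2, Prim1 and Rpa1 were called, Mcm5 with a rise of 1.83 (SE 0.50) and Cdt1 of 1.03 (SE 0.28), 24 passing adjusted over the list alone; adjusted p = 0.234 with an estimated correlation. The repair genes Brca1, Chek1, Palb2 and Rad50 rose by 1.64, 1.55, 0.53 and 0.44 (list median 0.21, 7 passing adjusted over the list alone), with adjusted p = 0.180 with an estimated correlation. Of the 5 measured histone genes H3c11 and H1f2 rose by 0.87 and 0.91 (list median 0.21), with adjusted p = 0.0703 with an estimated correlation. Macrophage markers lay higher in 14 of 18 (median 0.50, 9 passing adjusted over the list alone): the scavenger receptor Marco rose by 2.85 (SE 0.34, adjusted p = 4.36e-06), beside Adgre1, Cd5l, Cd68 and Spic at 0.67 to 0.85, with adjusted p = 0.234 with an estimated correlation. Knockout replicate 3 also stood apart in the replication genes, with a mean of 7.85 against 7.15 and 7.17 in the other knockout arrays, and without it the replication and repair medians were 0.18 and 0.12. The histone median was 0.46 without wild-type replicate 5 and the macrophage median 0.27 without wild-type replicate 4. Cdt1, Rfc2 and H1f2 lost their calls in 3 of 8 fits without single arrays, Palb2 in 2 and Brca1, H3c11 and Spic in 1, with adjusted p up to 0.340.

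Among metabolic genes of the E2f1/E2f2/E2f3 knockout, the cholesterol synthesis enzymes Fdft1 and Msmo1 rose by 1.53 (SE 0.28) and 1.25 (SE 0.33) (list median 0.52, 9 passing adjusted over the list alone), with adjusted p = 0.431 with an estimated correlation, and the desaturase Scd1 fell by 2.34 (SE 0.53) and Dgat2 fell by 0.31 (fatty acid synthesis median -0.35, 6 lower adjusted over the list alone), with adjusted p = 0.252. In the unfolded protein response list (median -0.46) Xbp1, Pdia6 and Calr fell by 0.96, by 0.58 and by 0.46, while Asns and Ddit3, which the amino acid response also induces, rose by 2.42 (SE 0.30) and 1.43 (SE 0.29), with adjusted p = 0.252 with an estimated correlation. Periportal genes lay higher (median 0.35, Hal at 0.89, Aldh1b1 at 1.43 and Etnppl at 1.31 called, 6 adjusted over the list alone), with adjusted p = 0.0540 with an estimated correlation. Orm2, Orm3 and Itih3 of the acute phase rose by 3.32 (SE 0.71), 1.76 (SE 0.29) and 0.49 (list median 0.17, 6 adjusted over the list alone), with adjusted p = 0.567 with an estimated correlation. Erythroid (0.09, Car2 called at 0.78) and fetal liver genes (0.12, Mest at 0.79 and Plagl1 at 0.72 called) had adjusted p = 0.231, and strain-variable genes (-0.08, with Glo1, H2-Aa and H2-Ab1 lower adjusted over the list alone) adjusted p = 0.234 with an estimated correlation. Without wild-type replicate 5 the fatty acid synthesis median was 0.01 and its call ended (adjusted p = 0.287), as did those of unfolded protein (median -0.29, 0.0783), fetal liver (0.180), erythroid and strain-variable genes. Without wild-type replicate 4 the calls of cholesterol synthesis (median 0.37, 0.112), acute phase (0.932) and strain-variable genes ended and the periportal median was 0.20. Knockout replicates 1 and 2 each decided the fetal liver and erythroid calls (0.137 for the latter without replicate 2), replicate 1 that of acute phase and replicate 3 that of strain-variable genes (0.537). The cholesterol median was 0.32 and 0.83 without replicates 2 and 3, and the acute phase median 0.42 without replicate 3. Further large changes were Nipal1, Ddit4, Cyp26a1, Cyp2b10, Slc15a2 and Tafa2, which rose by 2.13 to 3.00, and Serpina12, Gadd45a, Dio1, Slco1a1 and Slc25a30, which fell by 2.19 to 3.14. Plagl1 lost its call in 7 of 8 fits without single arrays, Cyp2b10 and Dio1 in 6, Msmo1 and Dgat2 in 4, Ddit4, Serpina12 and Slc25a30 in 3, Slco1a1, Calr and Scd1 in 2 and 8 others named here in 1, with adjusted p up to 0.289. In all 597 genes were called, 311 higher and 286 lower. The count was 4 with only the 5 arrays of this run, 9 with only the 2 groups, 189 with array weights and 6167 without a run term, and 362 without knockout replicate 3 and 245 without wild-type replicate 5. Genotype, Cre line and background differ together between these groups.

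The knockout of the repressing pair was set against that of the activating trio at 2 months, each relative to the wild-type arrays of its own run. The difference was called in 122 genes, 67 higher and 55 lower in the E2f7/E2f8 knockout. Orm2 stood at -4.67 log2 (SE 0.92), Marco at -3.43 (SE 0.45, adjusted p = 5.91e-05), the retinoic acid hydroxylase Cyp26a1 at -3.30 (SE 0.71), the asparagine synthetase Asns at -2.87 (SE 0.39) and Orm3 at -2.16 (SE 0.38). Gadd45a stood at 3.18 (SE 0.58), the major urinary protein Mup10 at 2.60 (SE 0.60), the aquaporin Aqp8 at 2.56 (SE 0.57), Bcl3 at 1.91 (SE 0.32) and Sdr9c7 at 1.86 (SE 0.37). Targets of p53 lay lower (median -0.32, Phlda3 at -1.16, Eda2r at -1.35 and Mdm2 at -0.65 called, Perp higher and Polk lower adjusted over the list alone), with adjusted p = 0.0725 with an estimated correlation. Macrophage markers lay lower in 16 of 18 (median -0.75, Marco, Cd5l, Adgre1 and Cd68 called, 13 adjusted over the list alone), with adjusted p = 0.194 with an estimated correlation. Male-biased genes lay higher in 15 of 15 (median 1.29, Cyp2u1 called at 1.27, 7 adjusted over the list alone), with adjusted p = 0.265, and female-biased genes lower (-0.62), with adjusted p = 0.317 with an estimated correlation. Replication genes lay lower in 45 of 54 (median -0.40), fatty acid synthesis genes higher (0.40) and unfolded protein genes higher (0.41, Calr called higher at 0.67 and Ddit3 and Asns lower), all with adjusted p = 0.416 with an estimated correlation. Acute phase (-0.29, Orm2 and Orm3 called) and interferon genes (0.26) had adjusted p = 0.483, stellate cell genes (-0.24, Acta2 called at 1.42 and Timp1 at -0.87) adjusted p = 0.467, DNA repair (-0.13) adjusted p = 0.320, periportal (-0.30) adjusted p = 0.317 and cholesterol synthesis genes (-0.35) adjusted p = 0.604 with an estimated correlation. Without E2f1/E2f2/E2f3 knockout replicate 3 the interferon call ended (median 0.03, adjusted p = 0.779), as did the periportal call (0.0907), and the replication, p53 and male-biased medians were -0.18, -0.16 and 0.79. The DNA repair median was -0.09 without that array and -0.21 without wild-type replicate 3. Without wild-type replicate 5 the fatty acid (median 0.16, 0.192) and unfolded protein calls (0.158) ended, the latter also without E2f7/E2f8 knockout replicate 1. Without wild-type replicate 4 the cholesterol (0.642), acute phase (0.585), stellate (0.249) and periportal calls ended, the acute phase call also without wild-type replicate 1. The cholesterol call held in 6 of 12 fits without single arrays. Cd5l lost its call in 8 of 12 such fits, Mup10 in 6, Mdm2 in 3, Cyp26a1 and Aqp8 in 2 and Calr, Cyp2u1, Gadd45a, Orm2, Sdr9c7 and Timp1 in 1, with adjusted p up to 0.157. The count of 122 was 17 with only the groups compared, 76 with array weights and 10351 without a run term. It was 74 without E2f7/E2f8 knockout replicate 3, 218 without E2f1/E2f2/E2f3 knockout replicate 1, and 79 without wild-type replicate 1 or replicate 2.

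Across genes the effects of the 2 knockouts correlated with r = 0.0791 and rho = 0.0660 (covariance 0.00286), with separate wild-type arrays. No gene was called in both, where independent lists give 0.0171 higher and 0.0157 lower. Without a run term all 5 wild-type arrays serve both groups, so the run difference alone pushes r negative. It was -0.560 (covariance -0.0498), which decides nothing. Unchanged groups simulated against shared controls gave 0.407 (0.375 to 0.440 over 100 draws) and 0.00549. With the replicate number as a block r was -0.133.

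**Figure D4:**
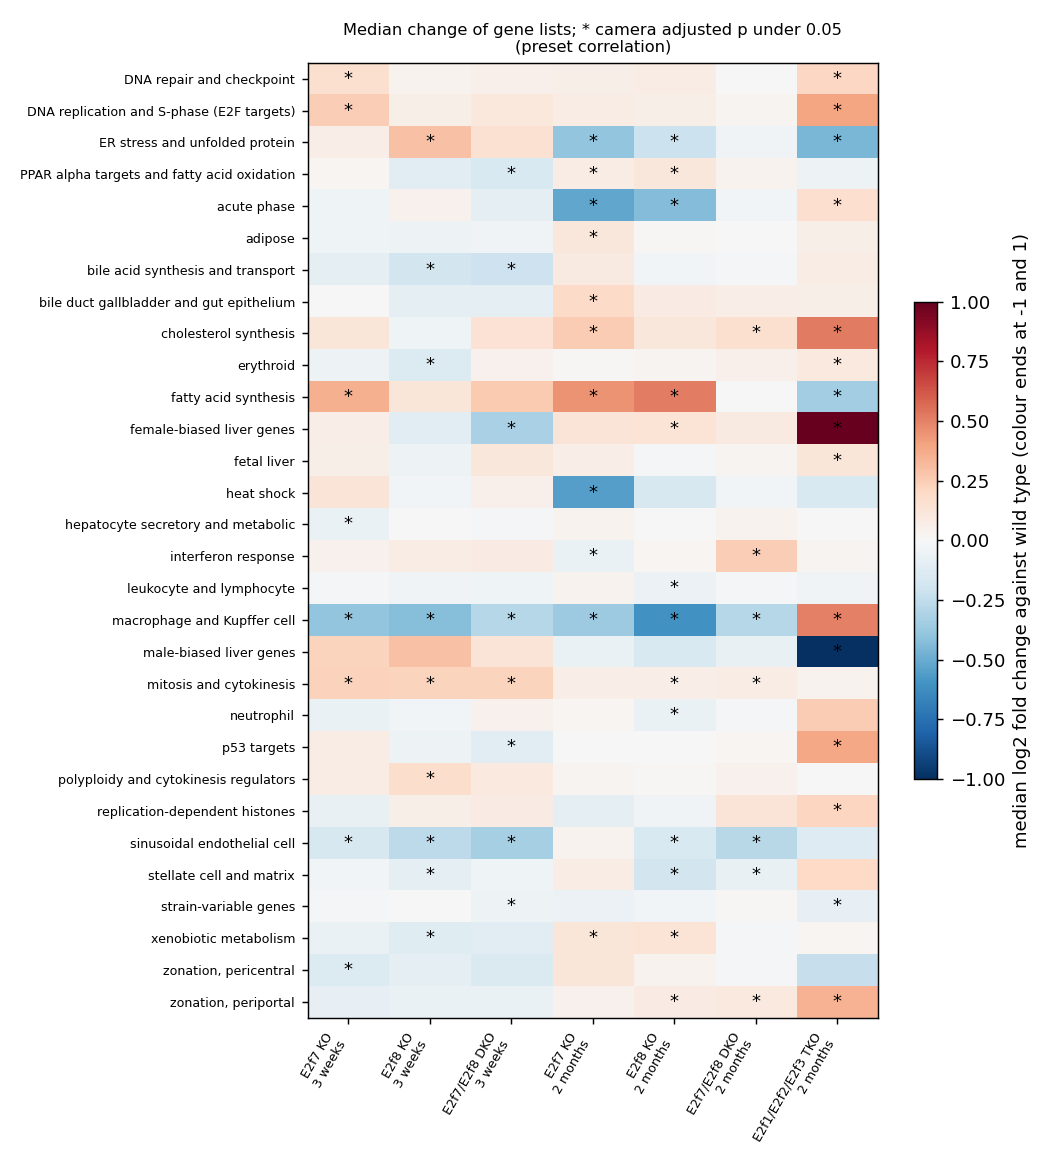
Median log2 change against wild type (colour, from -1 to 1) of the members of the gene lists (y axis) in the 7 knockout groups (x axis); a star marks a camera adjusted p under 0.05 with the preset correlation. The male-biased liver genes reached -1.50 and the female-biased 1.00 in the E2f1/E2f2/E2f3 knockout.

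Wild-type livers at 2 months (n = 3, replicates 1 to 3) and 3 weeks (n = 3) lie in separate normalization runs, so age and run differ together. After quantile normalization of all arrays Hao2, Slc22a27, Slc22a29 and Nox4 were still called, at -7.62, -6.79, -6.56 and 5.53, so the distributions of the runs alone do not make up these changes, but a batch effect on single genes cannot be told apart from age. Replicates 4 and 5 at 2 months entered only through the run term and the spread. The median change was 0.78 log2, and 16338 genes were called, 15908 higher and 430 lower. After quantile normalization 9114 were called, 4806 higher. Values, but not calls, are therefore given relative to the median of all genes. Female-biased liver genes lay far lower at 2 months (median -3.60 relative to all genes, 12 of 17 called lower and 1 higher, likewise adjusted over the list alone, camera adjusted p = 1.20e-38, adjusted p = 3.64e-05 with an estimated correlation). The sulfotransferase Sult2a2 stood at -8.24 relative to the median gene (SE 1.02), the hydroxyacid oxidase Hao2 at -7.48 (SE 0.16), Slc22a27 at -6.64 (SE 0.19), Cyp2b9 at -6.54 (SE 1.17) and Slc22a29 at -6.46 (SE 0.25). The NADPH oxidase Nox4 stood at 5.55 (SE 0.20), the oxysterol hydroxylase Cyp7b1 at 4.56 (SE 0.36), Ugt2b38 at 4.28 (SE 0.70), C6 at 4.06 (SE 0.39) and Saa2 at 3.88 (SE 0.84).

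Proliferation genes lay lower in wild type at 2 months relative to all genes. Mitosis genes had a median of -1.09 (camera adjusted p = 4.14e-41, adjusted p = 0.0241 with an estimated correlation). Of 62 raw changes 29 were called lower and 14 higher, and 29 and 13 adjusted over the list alone. Smc2 stood at -2.62 (SE 0.26) and Prc1 at -1.70 (SE 0.15). DNA replication genes had a median of -0.88 (adjusted p = 0.0404 with an estimated correlation). Of 54 raw changes 15 were called lower and 18 higher, 14 and 17 adjusted over the list alone. Mcm3 stood at -2.25 (SE 0.28) and Cdt1 at -2.11 (SE 0.25). Stellate cell and matrix genes had a median of -0.88 (Col4a1 at -2.41, Col6a3 at -1.80, adjusted p = 0.0127 with an estimated correlation), fetal liver genes -0.54 (Mest at -1.91, Gpc3 at -1.39, adjusted p = 0.00598), DNA repair genes -0.55 (Chek1 at -1.80, Rad51ap1 at -1.30, adjusted p = 0.0451), polyploidy regulators -0.49 (Racgap1 at -1.56, adjusted p = 0.0241) and PPAR alpha targets -0.36 (Acot3 at -3.26, Acot2 at -1.61, adjusted p = 0.0384). Cholangiocyte genes had a median of 0.02 above that of all genes but a camera direction of lower, set by members such as Pkhd1 at -2.07 and Cd24a at -1.91 (adjusted p = 0.0228 with an estimated correlation). E2F and retinoblastoma family genes (-0.18, Rbl1 at -2.43) and p53 targets (-0.28, Cdkn1a at -2.53 and Bbc3 at -1.17) had adjusted p = 0.0696, and fatty acid synthesis genes (-0.71, Elovl5 at -1.13) adjusted p = 0.0703 with an estimated correlation. Endothelial genes (-0.56, Lyve1 at -2.92) had adjusted p = 0.196, cholesterol synthesis genes (-0.57) adjusted p = 0.182, interferon genes (-0.31, Ifit2 at -1.35 and Gbp2 at -1.25) adjusted p = 0.235 and xenobiotic genes (-0.17, Cyp2c55 at -2.55) adjusted p = 0.104 with an estimated correlation. Leukocyte (-0.17, Gzma at -1.39) and periportal genes (-0.09) had adjusted p = 0.335 and 0.180 with an estimated correlation, and the leukocyte call ended without 3-week replicate 1 (adjusted p = 0.0530). Bbc3 and Elovl5 lost their calls in 4 of 8 fits without single arrays, E2f1 in 2 and Chek1, Gpc3 and Ifit2 in 1, with adjusted p up to 0.225. With the mean of a gene's probe sets in place of the brightest, the raw changes of E2f1, Chek1 and Rbl1 turned from -0.35, -1.02 and -1.65 to 0.17, 0.34 and 0.36 log2.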

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

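The tests of mixed sexes, of strain and Cre line, of a lower share of all non-hepatocyte cells and of alleles near E2f7 in the E2f8 knockout were chosen only after the results were seen. The criterion for excluding alleles near a targeted locus was also tightened after the ratios had been seen, from a ratio below 2 to an upper 95% bound below 2 both with and without the genes that overlap a targeted gene. The ratios given leave those genes out as part of the locus.

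For 4 of the 98 pairs of a named gene and a group of 4 arrays, 1 array lay far from the other 3. E2f2 was at 5.79 log2 in replicate 2 of the E2f7 knockout at 3 weeks, against 5.37 to 5.43 in the others. In replicate 1 of the E2f8 knockout at 3 weeks B4galnt1 was at 7.99, against 3.88 to 4.58, and Rgs16 at 4.99, against 5.77 to 5.78. E2f1 was at 6.97 in replicate 3 of the E2f7/E2f8 knockout at 3 weeks, against 6.74 to 6.78. Chance marks about 1 in 20 in this way, or 4.9 of 98.

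The effect of losing both E2f7 and E2f8 differed between the ages, by an interaction term in limma, for Pcdh17 (-1.03 log2, SE 0.18, adjusted p = 0.0394). With camera and the preset correlation 7 gene lists differed, as 2 months minus 3 weeks. The medians were -0.14 for mitosis (adjusted p = 0.00930, lower in 48 of 62 members), 0.18 for p53 targets (0.00930), 0.25 for interferon response (0.000300, higher in 32 of 37), 0.0512 for hepatocyte genes (0.0206), 0.18 for bile acid genes (0.0187), 0.33 for female-biased genes (0.00930, higher in 17 of 17) and 0.18 for periportal genes (0.0316). With an estimated correlation their adjusted p lay between 0.491 and 0.936, and each of the 7 lost its call in at least 1 of the 16 fits that left out an array. Without wild-type replicate 3 at 3 weeks the mitosis list had adjusted p = 0.934.

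Signal changed in probe sets that carry no single gene symbol and enter no other comparison. Of 10092 such probe sets limma called 19 in the E2f7 knockout, 37 in the E2f8 knockout and 75 in the E2f7/E2f8 knockout at 3 weeks. At 2 months it called 9 in the E2f8 knockout, each of them higher, and 111 in the E2f1/E2f2/E2f3 knockout.

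Other splits of the same arrays were fitted in the same way. The E2f8 knockout gave 347 genes at 3 weeks and 64 at 2 months, against at most 288 and 12 in other splits. At each age only the real split of 35 gave as many. For the interaction at 2 months 1 of 100 splits did (199, against at most 4), and for wild type between the ages 1 of 56 (15637 genes in a fit of wild-type arrays alone, against at most 2914 when the second run at 2 months was set apart with the 3-week arrays). Over 12 uncorrected comparisons chance stays open for these 4 counts, as do the normalization runs for the last. Chance stays open for the following counts too.

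In the E2f7 knockout 3 of 35 splits gave at least the real 8 genes at 3 weeks (highest other 317) and 4 of 35 gave the real 1 at 2 months (highest other 1). In the E2f7/E2f8 knockout 3 of 35 gave at least 118 at 3 weeks (highest other 216), and 8 of 35 gave at least 2 at 2 months (highest other 19). The comparison of the E2f7/E2f8 with the E2f1/E2f2/E2f3 knockout gave at least 122 in 9 of 100 splits (highest other 389), the interaction at 3 weeks at least 23 in 7 of 100 (highest other 192) and the change of the double loss with age at least 1 in 23 of 100 (highest other 32). Splits with several times the real count point to a structure of the samples beside genotype. The split with 317 genes set wild-type replicate 1 with 3 knockout arrays, and that with 216 set wild-type replicates 1 and 3 with 2. For the E2f1/E2f2/E2f3 knockout 2 of 10 splits gave at least 597 genes (highest other 846), and 10 splits are too few for a share under 0.05.

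In the E2f8 knockout 13 genes were called at both ages, and 5 of them lay near E2f7 or E2f8: B4galnt1, Rassf3 and Trhde near E2f7 on chromosome 10, and 0610005C13Rik and Pcsk6 near E2f8 on chromosome 7. At 2 months the share of called genes among the 199 nearest to E2f8 was 6.22 times that elsewhere (95% interval 2.28 to 17.0, Fisher's exact one-sided p = 0.00478), which is consistent with alleles carried along with the locus but rests on 4 genes, 2 of which, Saa1 and Saa2, are acute phase genes that moved with their list. Near E2f7 the ratio of 4.56 counts only B4galnt1, Rassf3 and Trhde, whose position prompted the test, so it decides nothing and alleles differing between the animals stay open. At 3 weeks the ratios of 1.87 near E2f8 (exact p = 0.0855) and 1.32 near E2f7 (exact p = 0.330) left alleles open, as did 1.18 in the E2f7/E2f8 knockout at 3 weeks (exact p = 0.471) and 1.34 in the E2f1/E2f2/E2f3 knockout (exact p = 0.0901), where the upper bound was 1.97 but 2.02 with Necab3, which overlaps E2f1. An effect of E2f8 loss alike with and without E2f7 was argued against for Trhde, by limma interactions of 2.14 and 1.60 at the 2 ages (adjusted p = 0.000398 and 0.00396), and less firmly for B4galnt1, by 4.00 (0.0661) and 3.57 (0.0438), while an effect that needs E2f7, or on the other 3 genes, stays open.

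Male-biased liver genes lay lower in the E2f1/E2f2/E2f3 knockout, with a median of -1.50. A shift set by replicate 3 alone was argued against by camera without it, with adjusted p = 1.81e-07 and a median of -0.76, though its size depends on that array and with an estimated correlation the list did not pass over all arrays (adjusted p = 0.0703). Animals of both sexes were argued against by the spans of Xist and of the mean of Y-linked genes over the 5 arrays of the run, the larger 0.371 log2 and the other 0.282. Strain background or Cre line stayed open: the strain-variable list had a median of -0.0788, but strain, Cre line and genotype differ together, so they cannot be told apart. Loss of the 3 genes is the biological explanation that the design gives, and it stays open for the same reason.

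Macrophage markers lay lower in the E2f7/E2f8 knockout at 3 weeks, with a median of -0.28. A shift set by 1 wild-type array was argued against: with each left out in turn the highest camera adjusted p was 0.0240, without replicate 3, where the median was -0.16, though with an estimated correlation the list did not pass over all arrays (adjusted p = 0.479). A lower share of every non-hepatocyte cell type stayed open, since 3 of the 6 other lists of such cells had a median above 0 but 0 were called higher by camera. An effect of E2f7 and E2f8 loss on macrophages was not tested apart from cell numbers and stays open.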

How the results depend on the processing

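The planned fit without a run term became an alternative after the distributions were seen. Fits with only the arrays of 1 run were chosen after the data were seen. Counts are of genes called by limma, 8, 347 and 118 at 3 weeks and 1, 64 and 2 at 2 months for the E2f7, E2f8 and E2f7/E2f8 knockouts, 597 for the E2f1/E2f2/E2f3 knockout and 122 for the difference of the last 2 knockouts. They were 23 and 199 for the interactions at 3 weeks and 2 months, 1 for the change of the double loss with age and 16338 for wild type between the ages. Without the intensity trend every count stayed within 1.5 times these. Of genes with an unadjusted p under 0.05, 910 are expected with no change. They numbered 739 for the E2f7/E2f8 knockout at 2 months, 2036 for the E2f7 knockout at 3 weeks, 1279 for it at 2 months and 1325 for the change with age.

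With only the groups compared, 3-week counts were 0, 23 and 1 in the E2f7, E2f8 and E2f7/E2f8 knockouts and 2 for the interaction. With only same-run arrays these were 0, 125, 3 and 2. At 2 months the first fit gave 0, 35 and 9 in the E2f7, E2f8 and E2f1/E2f2/E2f3 knockouts. It gave 17 for the difference of the knockouts and 0 for the change with age. The second gave 111 in the E2f8 and 4 in the E2f1/E2f2/E2f3 knockout and 287 for the interaction. Fewer arrays estimate the spread in both, yet 64 and 199 rose to 111 and 287, so array number alone does not set counts. Of 190 calls of named genes 121 ended in the first, and of 136 in the second 88.

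Without a run term the spread of the wild-type arrays between the runs enters the error, and the E2f1/E2f2/E2f3 knockout is set partly against another run. The counts were 2, 115 and 8 for the E2f7, E2f8 and E2f7/E2f8 knockouts at 3 weeks, 40, 282 and 6 for them at 2 months, 6167 for the E2f1/E2f2/E2f3 knockout, 10351 for the difference and 1 for the interaction at 3 weeks. Yae1d1 turned to 0.70 in the E2f1/E2f2/E2f3 knockout, E2f2 to -1.23 in the difference of the knockouts and Gbp2 to 0.28 in wild type with age, and the correlation of the effects of the 2 knockouts turned to r = -0.560.

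After quantile normalization of all 35 arrays the counts were 57 for the E2f7/E2f8 knockout at 3 weeks (37 higher), 3 for the E2f7 knockout at 2 months, 9114 for wild type with age (4806 higher) and 0 for the change of the double loss with age. E2f2 turned to -0.67 in wild type with age. Of the 103 genes in the difference of the knockouts 46 were higher, against 67 of 122. This normalization removes by construction the median shift of 0.78 in wild type with age; for the others the cause was not tested.

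Without dim genes the counts were 64 for the E2f7/E2f8 knockout at 3 weeks (32 higher), 9608 for wild type with age, where fewer genes were tested, and 0 for the change with age. Signal near background limits what can be seen of dim genes. With the mean of a gene's probe sets they were 0 for the E2f7 and 1 for the E2f7/E2f8 knockout at 2 months and 0 for the change with age, and E2f1, Chek1 and Rbl1 turned to 0.17, 0.34 and 0.36 in wild type with age. With array weights they were 19, 161 and 38 for the E2f7, E2f8 and E2f7/E2f8 knockouts at 3 weeks, 59, 252 and 13 for them at 2 months, 189 for the E2f1/E2f2/E2f3 knockout, 76 for the difference and 582 for the interaction at 2 months. The cause was not tested.

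With the replicate number as a block the counts were 35 for the E2f7 and 185 for the E2f7/E2f8 knockout at 3 weeks, 0 for the E2f7, 41 for the E2f8 and 98 for the E2f1/E2f2/E2f3 knockout at 2 months and 25 for the difference. Elovl5 turned to 0.87 in wild type with age, and the correlation of the 2 knockouts' effects to r = -0.133. The numbers did not pair the arrays: residuals of arrays with the same number had a mean r of 0.000629 (42 pairs) and of others -0.000200 (132 pairs), and in 13 of 42 searches of another group for an array's best match it had the same number. Of the 190 calls of named genes 74 ended or turned, and the cause was not tested.

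Leaving out single arrays gave 1 to 265 genes for the E2f7, 166 to 396 for the E2f8 and 13 to 549 for the E2f7/E2f8 knockout at 3 weeks, and 0 to 39, 7 to 100 and 2 to 5 at 2 months. It gave 245 to 767 for the E2f1/E2f2/E2f3 knockout, 74 to 218 for the difference, 16028 to 16359 for wild type with age, 8 to 31 and 60 to 268 for the interactions at 3 weeks and 2 months and 0 to 4 for the change with age. The highest counts of the E2f7 and E2f7/E2f8 knockouts at 3 weeks came without wild-type replicate 1. Correlation of effects ranged from 0.135 to 0.274 between the ages and from -0.00909, without wild-type replicate 3, to 0.142 between the knockouts. Where 1 wild-type array of the second run was left, it was assumed to vary like the other groups. The effects of the E2f7/E2f8 knockout at the 2 ages correlated with r between 0.200 and 0.217 in the other alternatives, and with those of the E2f1/E2f2/E2f3 knockout between 0.0757 and 0.121 where it was not negative.

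Of the gene lists called by camera, 15 kept and 112 lost their call with an estimated correlation, 85 and 42 without a run term, 107 and 20 after quantile normalization, 102 and 25 with the block, 101 and 26 without dim genes, 118 and 9 with the mean of probe sets and 121 and 6 with array weights. Leaving out single arrays moved the median by over 1.5 times for 75 of 109 called lists, wild type with age aside. It turned the sign for 3, fatty acid synthesis in the E2f1/E2f2/E2f3 knockout, interferon response in the E2f7 and neutrophil genes in the E2f8 knockout at 2 months. A sex covariate was not run, and the wild-type arrays were not split in further ways for the comparison of the knockouts.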

Other observations

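Every value in this part was picked after the results were seen, and no explanation was tested. In the E2f1/E2f2/E2f3 knockout single markers changed within lists that camera did not call. The bile acid enzymes Cyp7a1 and Akr1d1 rose by 1.83 (SE 0.37, limma adjusted p = 0.00385) and 0.97 (SE 0.20), and the metabolic coactivator Ppargc1a by 1.58 (SE 0.37). The lymphatic and sinusoidal marker Lyve1 rose by 1.68 (SE 0.36), while the endothelial receptors Tek and Tie1 fell by 0.92 (SE 0.23) and fell by 0.48 (SE 0.13). Acta2, a marker of activated stellate and smooth muscle cells, fell by 1.57 (SE 0.27, adjusted p = 0.000716), and Timp1 and Rgs5 rose by 0.85 (SE 0.14) and 0.84 (SE 0.23). The MHC class II genes Cd74 and H2-Eb1 fell by 0.87 (SE 0.23) and fell by 0.64 (SE 0.13). The lists had camera adjusted p = 0.306 for bile acid genes, 0.0544 for gluconeogenesis, 0.0863 for endothelial, 0.0680 for stellate and 0.240 for leukocyte genes.

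Yae1d1 stood between 0.57 and 0.69 log2 above wild type in the 6 groups without E2f7, E2f8 or both. With the mean of its probe sets it stood at 0.22, 0.22 and 0.17 in the E2f7, E2f8 and E2f7/E2f8 knockouts at 3 weeks and at 0.21, 0.24 and 0.27 at 2 months, and without a run term at 0.11, 0.16 and 0.17 at 2 months. It was called in none of the 6 under either setting, with limma adjusted p between 0.153 and 0.785. Its signal in wild type at 2 months was 7.63, 7.62 and 7.84 in the first run and 9.05 and 8.96 in the second, where the E2f1/E2f2/E2f3 knockout had 8.91, 8.87 and 8.99. The interaction of the 2 losses was -0.60 (SE 0.14, adjusted p = 0.0661) at 3 weeks and -0.62 (SE 0.14, adjusted p = 0.0164) at 2 months.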
